A study of Mus musculus with 8 samples.

How the data were processed

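RNA from the dorsal horn of the lumbar spinal cord of adult C57BL/6J mice was measured in 8 libraries, 4 from wild-type mice and 4 from mice without miR-96, a microRNA of the cluster that also holds miR-182 and miR-183. Per the labels' protocols, polyadenylated RNA was made into libraries with a NEBNext Ultra kit. Per the submitters' processing notes, HISAT2, SAMtools and Cufflinks were used; their versions and options, and whether strand was used in counting, are not given in the sources used here. The authors deposited FPKM per gene, a unit in which fragment counts are already divided by transcript length and by the number of mapped fragments of the library. Per the file headers, each gene came with an identifier, an FPKM value and a locus. The same 49585 gene identifiers stood in each library, 49326 of them with a symbol in the annotation used here (GENCODE, mouse assembly GRCm38). The submitters' processing notes list the genome build mm8, but the deposited locus equalled the GRCm38 annotation for 45128 genes, 91.5% of those with a symbol, so coordinates below are on GRCm38, numbered from 1.

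Read counts were not used here. FPKM of low genes fall on steps of 1 fragment, and genes with a single annotated transcript of at least 3000 nt were used to estimate the depth of each library from those steps, with an assumed mean fragment length of 200 nt. Between 97.9% and 99.4% of the values used lay within 0.15 of a whole number of fragments, against 30% by chance. The estimates ran from 32000000 to 43100000 fragments per library and hold only as far as that assumption. Because FPKM are not counts, no count model was fitted.

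The comparison of knock-out with wild type used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options, two-sided) on log2(FPKM + 1). A fold change on this scale understates the change of low genes. Genes with a mean FPKM of at least 1 over the 8 libraries were tested (15061 genes), and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Gene identifiers that share a symbol were kept apart. The 34 gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over lists with at least 4 tested members, and again with an estimated correlation. The test of the list of sodium channels was also read alone, without that adjustment, since the series asks about these genes. Genes whose longest annotated 3′ untranslated region (UTR, at least 50 nt) holds a match to miR-96 positions 2 to 8 (GTGCCAA) or its 7-base form ending in A (TGCCAAA) were compared with other genes in a linear model with log2 UTR length and UTR GC content, and the difference was set against all 35 splits of the 8 libraries into groups of 4. Each of the 16384 heptamers was scored in the same model. For 10 lists the mean was also ranked among 10000 random lists, each member replaced by 1 of the 50 protein-coding genes nearest in transcript length and mean level. Positions on chromosomes were tested with Fisher's exact test. Since no gene passed the adjusted threshold, genes with unadjusted p under 0.05 took the place of changed genes there.

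Tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule takes the 10 genes of largest fold change in each direction among those past the threshold, filled up with the genes of lowest unadjusted p as values only, every sodium channel gene tested (1 of the 10 is not reported here by itself), and up to 4 members of lowest p from each other list. Predicted gene models, identifiers and pseudogenes were counted but not named (1954 tested genes). The lists were voltage-gated sodium channels, voltage-gated calcium channels, voltage-gated potassium and HCN channels, glutamate receptors, GABA-A and glycine receptors, reported miR-96 targets, genes next to the cluster, sex-linked genes, opioid and tachykinin signalling, immediate early genes, cytokines and chemokines, interferon-induced genes, heat shock and chaperone genes, cholesterol synthesis, synaptic vesicle and release machinery, neurofilament and axonal cytoskeleton, ribosomal protein genes, mitochondrially encoded genes, respiratory chain genes, histone genes, and markers of 14 cell types. The ribosomal list was fixed as a rule on symbols, and 2 readings of that rule were run. The first took 98 genes, some of them not ribosomal proteins. The second, adopted after the values of the first had been seen, kept to the wording of the rule (digits and at most 1 letter) and took 79 genes, and the closing section gives both. The 79 still include Rpl6l, annotated as a processed pseudogene, because pseudogenes were left out only by the symbol ending -ps. Lists of genes expressed in liver, skeletal muscle, kidney and pancreas were written after the data had been seen.

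Alternatives planned beforehand were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, median-ratio rescaling, quantile normalization, limma without trend and robust options, estimated library weights, the replicate number as a block, and each library left out in turn. Count-based alternatives written for the case of raw counts did not apply to FPKM. Removing each library's trend on transcript length, and on length and then transcript GC content (loess, span 0.5), was added after the data had been seen, as were the wider reading of the ribosomal rule and the estimated correlation under each other setting. Replicate numbers 1 to 4 occur in both groups, and the labels do not say that they pair animals.

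The fit was tested on simulated data for 15061 genes, 200 of them changed. With changes added to the deposited values, 19.4% of genes changed by 0.5 on the log2 scale, 88.1% of those changed by 1 and 100% of those changed by 2 passed the adjusted threshold. So did 8 genes given no change. The libraries kept their real labels there, so these 8 may differ as deposited and are not a count of false calls. With independent noise of each gene's own residual SD, 22.4%, 82.1% and 100% passed, with 4 unchanged genes. Tables were prepared with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3) and plots drawn with matplotlib 3.10.9.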

Results

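The series compared the transcriptome of the lumbar spinal dorsal horn, the part of the cord that receives pain and touch input, between wild-type mice and mice without miR-96. Its title asks whether miR-96 holds voltage-gated sodium channels down in the cord and so prevents allodynia, pain from touch that is normally harmless. There were 8 polyA RNA-seq libraries, 4 per genotype. The labels number the libraries of each genotype without saying whether each came from a separate animal, so p-values measure the spread between these libraries, which may in part be technical. Between 24091 and 25560 genes had a value above 0 per library, and the estimated depth was 32000000 to 43100000 fragments, at which genes under a mean of 1 FPKM were not tested.

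The targeted gene, Mir96 (chromosome 6, 30169446 to 30169551, minus strand, within a cluster with Mir182 and Mir183), was listed at 0 FPKM in all 8 libraries, as were Mir182 and Mir183. A polyA library of long RNA does not measure mature microRNAs, so these values check nothing about the genotype labels. Values below are FPKM as mean ± SD over the 4 libraries of a genotype, and fold changes are log2 values, knock-out minus wild type, with limma standard errors (SE).

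No gene differed between the genotypes past limma's adjusted p of 0.05 among 15061 genes tested, and 831 genes had an unadjusted p under 0.05. Leaving out 1 library gave between 325 (without knock-out replicate 1) and 3151 (without wild type replicate 4) such genes. Genes of plasma proteins made mainly in liver had the lowest p, and each of those named here had all 4 knock-out libraries above every wild-type library, a separation that chance gives in either direction for a share of 0.0286 of genes. The genes were chosen for their low p, so this separation adds no separate support. Alb, serum albumin (chromosome 5, 90460897 to 90476602), was at 2.42 ± 2.91 FPKM in wild type and 23.1 ± 9.11 in knock-out, a log2 fold change of 3.23 (SE 0.62, limma adjusted p = 0.62). Hp, haptoglobin (chromosome 8, 109575128 to 109579172), was at 0.363 ± 0.203 and 2.98 ± 1.01 FPKM, a log2 fold change of 1.52 (SE 0.20, adjusted p = 0.159). Ambp, which encodes the precursor of a plasma glycoprotein and bikunin (chromosome 4, 63143275 to 63154799), had the lowest p, with 0.184 ± 0.207 and 2.01 ± 0.505 FPKM and a log2 fold change of 1.35 (SE 0.17, adjusted p = 0.159). The alpha-1-antitrypsin gene Serpina1e, hemopexin (Hpx), the plasma protease inhibitor Pzp and apolipoprotein A-I (Apoa1) had log2 fold changes of 1.74, 1.61, 1.02 and 1.52. Wild-type libraries were not free of these transcripts: Alb was at 3.69 and 5.94 FPKM in wild type replicates 1 and 2 and at 0.0303 and 0.0301 in replicates 3 and 4, while the knock-out libraries held 11.7, 20.7, 33.0 and 27.1. Without knock-out replicate 2, Hpx was the single gene past the threshold (log2 fold change 1.84, limma adjusted p = 0.0487). With estimated library weights, 1627 genes passed, 1012 higher and 615 lower in knock-out. Of the 35 splits of the libraries, 6 gave as many under weights, the real one included.

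**Figure D1:**
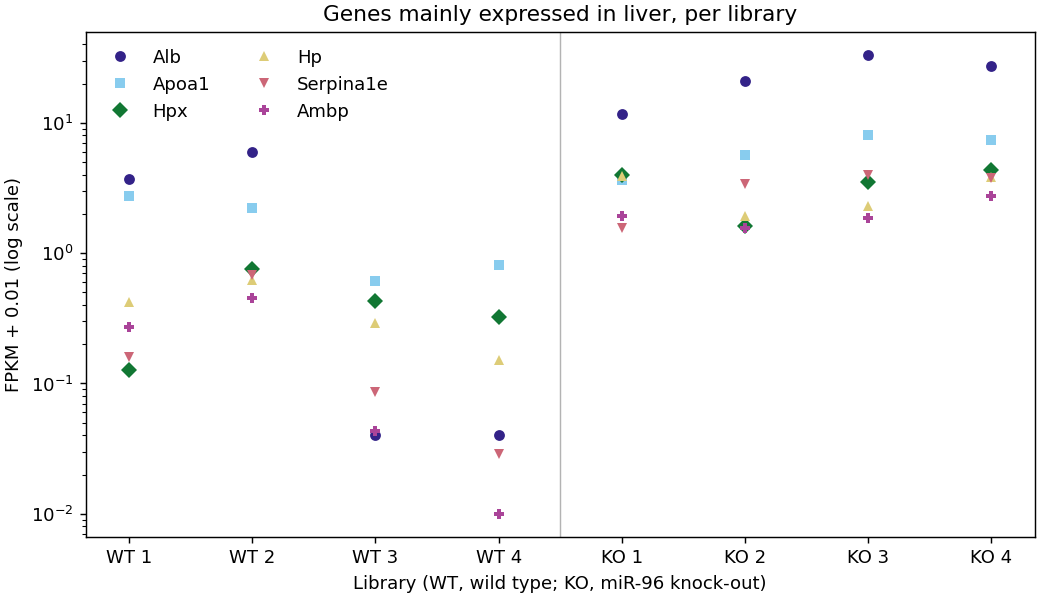
FPKM plus 0.01 (log axis) of 6 genes mainly expressed in liver in each of the 8 libraries. In knock-out libraries Alb lay between 11.7 and 33.0 FPKM, and in wild-type libraries between 0.0301 and 5.94.

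The other 3 genes of the 10 with lowest p and higher values in knock-out were small noncoding genes: Mir8103 (5.02 ± 0.713 and 10.04 ± 1.90 FPKM), Snora23 (0.70 ± 0.486 and 2.38 ± 0.284) and Snord37 (4.16 ± 0.892 and 9.04 ± 2.64). They span 107, 184 and 64 nt, lengths at which FPKM from a long-RNA library is uncertain. The 10 genes of lowest p with lower values in knock-out differed by less than the liver genes did. Ttc23 was at 3.61 ± 0.334 FPKM in wild type and 2.44 ± 0.153 in knock-out (log2 fold change -0.42, SE 0.11), the histone gene Hist1h4h at 5.40 ± 0.910 and 3.26 ± 0.814 (-0.60, SE 0.16), and Bbc3, which encodes the pro-apoptotic protein PUMA, at 9.15 ± 1.02 and 6.85 ± 0.551 (-0.37, SE 0.11). Dgat2, an enzyme of triglyceride synthesis, was at 24.2 ± 3.75 and 17.99 ± 1.36 FPKM (-0.40, SE 0.12). The remaining genes were Efna1 (-0.48), March11 (-0.42), Hist1h4i (-0.38), Gstm4 (-0.35) and the protein phosphatase 2A genes Ppp2cb (-0.32) and Ppp2r3c (-0.30). Each of these 10 had an adjusted p of 0.62 in limma.

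The question of the series was whether sodium channel transcripts differ. Of the 14 genes listed, 10 were expressed above the filter, 8 of them with a higher mean in knock-out, and none passed the adjusted threshold over all genes or adjusted over the list alone (0 of 10 in limma in both, 1 at unadjusted p under 0.05, lowest adjusted p over the list alone 0.204). The channel most abundant among the pore-forming subunits, Scn8a (chromosome 15, 100869858 to 101045938), was at 119 ± 28.9 FPKM in wild type and 145 ± 11.3 in knock-out (log2 fold change 0.32, SE 0.18). Scn2a (chromosome 2, 65620771 to 65767447) was at 22.2 ± 6.36 and 30.3 ± 2.73 FPKM (0.47, SE 0.17, limma adjusted p = 0.62), Scn1a (chromosome 2, 66270778 to 66440840) at 62.9 ± 15.5 and 80.1 ± 11.6 (0.37, SE 0.18), Scn3a (chromosome 2, 65457118 to 65567627) at 4.76 ± 1.26 and 5.91 ± 0.617 (0.28, SE 0.15), and Scn9a (chromosome 2, 66480080 to 66634962), the channel Nav1.7 known from inherited pain disorders, at 1.37 ± 0.356 and 2.03 ± 0.477 (0.35, SE 0.16). The sodium channel-like gene Scn7a had a log2 fold change of 0.22 (SE 0.17). For the auxiliary beta subunits Scn2b, Scn3b and Scn4b the log2 fold changes were smaller in size than their SE, at 0.091 (SE 0.15), 0.053 (SE 0.13) and -0.023 (SE 0.13). Wild type replicate 1 held 77.0 FPKM of Scn8a, against 124 to 139 in the other wild-type libraries. Without it the log2 fold changes were 0.12 for Scn8a, 0.21 for Scn1a, 0.13 for Scn7a and -0.046 for Scn2b. With estimated library weights Scn2a (0.52, limma adjusted p = 0.0389), Scn9a (0.56, 0.0389) and Scn1a (0.34, 0.0467) passed. Scn8a was then at 0.14. These weights rested the wild-type mean mainly on replicate 3 (weight 5.09, against 0.153, 0.988 and 0.423 for replicates 1, 2 and 4). With weights, 6 of the 35 splits, the real one included, gave as many genes past the threshold as the real grouping.

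As a list, the sodium channel genes had a mean log2 fold change of 0.19 (SD over members 0.21), with a camera p of 0.0171 read alone and 0.0527 adjusted over the 34 lists. The adjusted p was under 0.05 without the filter (0.0429), with median-ratio rescaling (0.0498), with quantile normalization (0.0127) and with the replicate number as a block (0.0429). It was also under 0.05 without wild type replicate 2 (0.0456) or 4 (0.0146, mean 0.27). With an estimated correlation the p was 0.219 and the adjusted p 0.768. Neither this list nor any other passed with an estimated correlation under the other settings (lowest adjusted p 0.565, without wild type replicate 4). Wild type replicate 1 had the lowest list mean of the 8 libraries, 4.54 on the log2(FPKM + 1) scale against 4.82 to 5.05 in the other wild-type libraries and 4.94 to 5.04 in knock-out. Without it the mean log2 fold change was 0.10 (limma camera adjusted p = 0.401). With the length trend of each library removed, it was 0.038 (limma camera adjusted p = 0.652), and with the length and GC trends removed 0.0078.

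**Figure D2:**
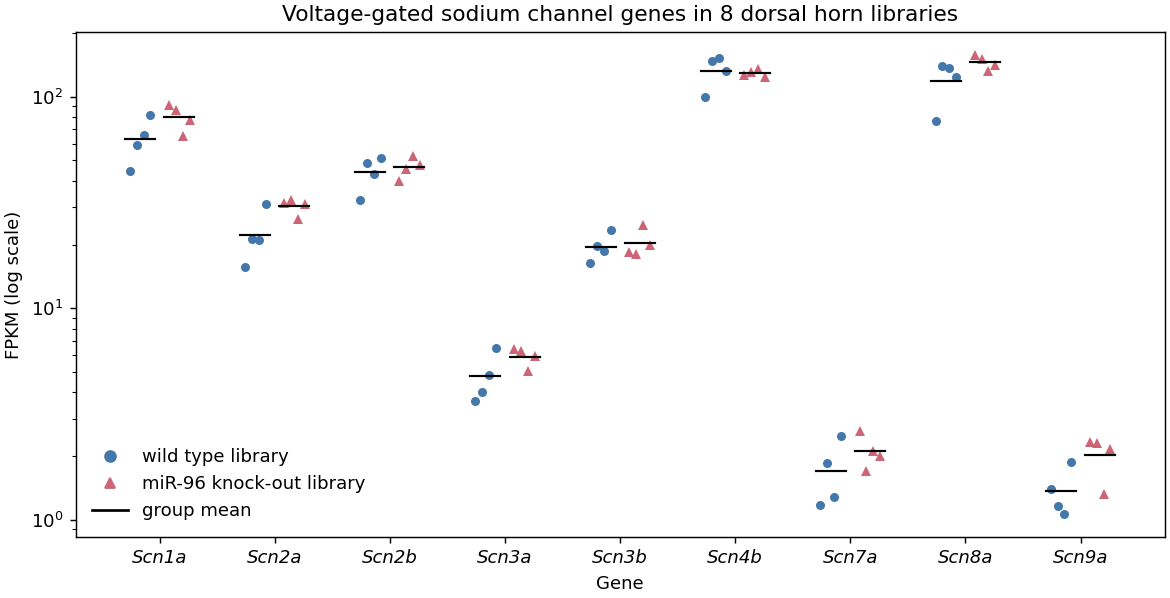
FPKM (log axis) of 9 of the 10 sodium channel genes tested, 1 point per library, with a bar at each group's mean. For Scn2a the wild-type mean was 22.2 and the knock-out mean 30.3, and libraries of both genotypes overlapped.

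Other neuronal channel and receptor lists had higher values in knock-out. Calcium channel genes had a mean log2 fold change of 0.18 (15 of 16 members higher, camera adjusted p = 0.00805, or adjusted p = 0.768 with an estimated correlation), with Cacna1b (0.26, SE 0.11), which encodes the N-type channel of presynaptic terminals, Cacna1c (0.33, SE 0.15) and Cacna1e (0.30, SE 0.13), while the beta subunit gene Cacnb3 was at -0.24 (SE 0.11). Glutamate receptor genes had a mean of 0.16 (20 of 22 higher, adjusted p = 0.0347, or 0.768 with an estimated correlation), among them Grm5 (0.36, SE 0.15) and Gria2 (0.53, SE 0.25). GABA-A and glycine receptor genes, which encode the inhibitory receptors, had a mean of 0.29 (13 of 15 higher, adjusted p = 0.0354, or 0.768 with an estimated correlation), led by Glra1 (1.55, SE 0.73), Gabrb2 (0.99, SE 0.48) and Gabrb1 (0.37, SE 0.16). In Glra1 a single library stood far off, wild type replicate 1 with 3.33 FPKM against 22.8 to 88.1 in the other 7. Reported miR-96 targets, a list fixed from knowledge of other tissues, had a mean of 0.14 (16 of 19 higher, adjusted p = 0.0287, or 0.768 with an estimated correlation), among them Odf2 (0.28, SE 0.087), Nr3c1 (0.19), Zeb1 (0.18), Foxo1 (0.024) and Foxo3 (0.11). Odf2, the member of lowest p, held no miR-96 site in its longest 3′ UTR. The 7 members with a site that joins both 7-base forms had a mean of 0.043, from -0.084 for Slc1a1 to 0.19 for Adcy6. The 10 with another site had a mean of 0.18, from -0.15 for Ryk to 0.31 for Cacna2d1, and the 2 without a site 0.25. These groups were compared after the values had been seen, without a test. Potassium and HCN channel genes, with Kcnq3 at 0.49 (SE 0.16), Kcna2 at 0.32 and Hcn2 at -0.24, did not pass as a list (mean 0.18, 18 of 27 higher, adjusted p = 0.0899). They passed with quantile normalization (0.0127) and without wild type replicate 2 (0.0441) or 4 (0.0146). None of the 4 lists called had a member past the threshold in limma over all genes or adjusted over the list alone (0 members in each, with 2, 1, 1 and 1 at unadjusted p under 0.05). None held without wild type replicate 1. The means were then 0.096 for calcium channels, 0.072 for glutamate receptors, 0.17 for GABA-A and glycine receptors and 0.066 for the reported targets (adjusted p = 0.0673, 0.41, 0.0673 and 0.209). Of the other libraries left out in turn, wild type replicate 3 ended the glutamate receptor and GABA-A calls (0.116 for both), wild type replicate 2 the GABA-A (0.111) and target calls (0.0507), and knock-out replicate 1 the GABA-A (0.0602) and target calls (0.0611). Knock-out replicate 4 left out ended the glutamate receptor (0.0604) and GABA-A calls (0.0635), and knock-out replicate 2 the glutamate receptor call (0.0568). Without wild type replicate 4 the glutamate receptor mean was 0.25 (adjusted p = 0.00127). The GABA-A call also ended without the filter (adjusted p = 0.0914) and the target call with library weights (0.0576). With the length trend removed none of the 4 held (adjusted p = 0.157 for GABA-A and glycine receptors and 0.971 for each of the others). With the length and GC trends removed, the means were -0.0031 for calcium channels, -0.0040 for glutamate receptors, 0.13 for GABA-A and glycine receptors and -0.019 for the reported targets.

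Ribosomal protein, nuclear respiratory chain, cholesterol synthesis and histone genes had lower values in knock-out, while mitochondrially encoded genes had a mean of 0.17 (8 of 16 higher) and did not pass. Ribosomal protein genes had a mean log2 fold change of -0.34 (79 of 79 members lower, camera adjusted p = 2.63e-17, or adjusted p = 0.768 with an estimated correlation), for example Rpl27 (373 ± 108 FPKM in wild type, 276 ± 8.38 in knock-out, -0.39, SE 0.17). Rpl17 differed most (142 ± 49.5 and 66.5 ± 51.4 FPKM, -1.27, SE 0.42), with 143 FPKM in knock-out replicate 3 against 34.1 to 45.2 in the other knock-out libraries. Genes named as respiratory chain subunits, a list by symbol that also takes in assembly factors, had a mean of -0.23 (88 of 96 lower, adjusted p = 7.87e-16, or 0.768 with an estimated correlation), for example Sdhd (-0.32, SE 0.13) and Ndufs3 (-0.27, SE 0.11) among subunits and Sdhaf4 (-0.40, SE 0.16) and Ndufaf3 (-0.41, SE 0.18) among assembly factors. Cholesterol synthesis genes had a mean of -0.14 (17 of 21 lower, adjusted p = 0.00226, or 0.768 with an estimated correlation), among them Fdft1, squalene synthase, with 41.4 ± 6.72 and 32.1 ± 3.96 FPKM (-0.35, SE 0.14), Ebp (-0.28, SE 0.12), Dhcr7 (-0.30, SE 0.13) and Mvk (-0.30, SE 0.14). Histone genes had a mean of -0.12 (15 of 18 lower, adjusted p = 0.0151, or 0.768 with an estimated correlation), with Hist1h4h at -0.60. In these 4 lists no member passed limma's threshold over all genes or adjusted over the list alone (0 members in each, with 2 ribosomal, 3 respiratory chain, 2 cholesterol synthesis and 2 histone genes at unadjusted p under 0.05). Wild type replicate 1 had the highest ribosomal list mean, 8.55 against 7.43 to 7.82 in the other 7 libraries. Without it the list means were -0.11 for ribosomal (adjusted p = 9.15e-08), -0.094 for respiratory chain (2.53e-08), -0.12 for cholesterol synthesis (0.000227) and -0.066 for histone genes (0.083). The cholesterol synthesis call also ended without wild type replicate 3 (mean -0.089, adjusted p = 0.0734) and the histone call without knock-out replicate 1 (0.0602). The histone call ended too without the filter (mean -0.0097, adjusted p = 0.682), with library weights (-0.087, 0.0693) and with the length trend removed (-0.035, 0.4).

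**Figure D3:**
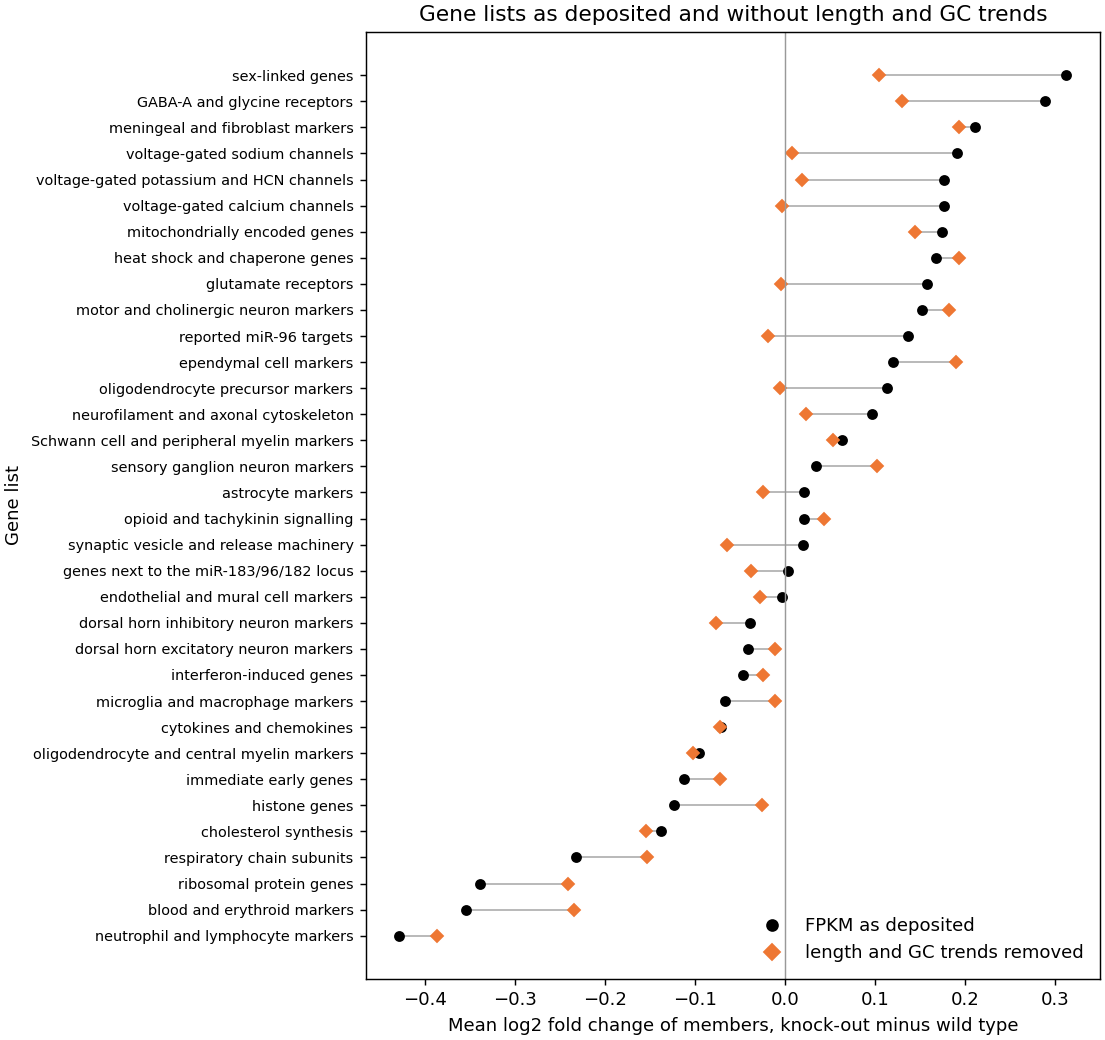
Mean log2 fold change (knock-out minus wild type) of each of the 34 gene lists from FPKM as deposited (circles) and with each library's trends on transcript length and GC content removed (diamonds). The sodium channel list lay at 0.19 as deposited and at 0.0078 with the trends removed, and the cholesterol synthesis list at -0.14 and -0.15.

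No list of cell-type markers passed (0 of 14 in limma's camera, with 1 at unadjusted p under 0.05). Excitatory dorsal horn markers had a mean log2 fold change of -0.041 (8 of 18 higher, camera adjusted p = 0.493), with the transcription factor Maf at 0.34 (SE 0.12), Reln at 0.34 (SE 0.19), and the neuropeptide genes Tac2 at -0.26 (SE 0.15) and Sst at -0.28 (SE 0.18). Inhibitory markers had a mean of -0.039 (8 of 16 higher, adjusted p = 0.243), with the neuropeptide genes Npy at -0.37 (SE 0.15) and Gal at -0.33 (SE 0.14) and the vesicular GABA transporter Slc32a1 at -0.16 (SE 0.081). Glial lists did not pass, with camera adjusted p of 0.286 for mature oligodendrocytes (mean -0.10), 0.388 for their precursors (0.11, with Vcan at 0.41, SE 0.13), 0.708 for astrocytes (0.021) and 0.388 for microglia and macrophages (-0.067). Motor and cholinergic (0.15, adjusted p = 0.708), sensory ganglion (0.034, 0.83), endothelial and mural (-0.0032, 0.909), Schwann cell (0.064, 0.83) and ependymal markers (0.12, 0.788) did not pass either. All 13 meningeal and fibroblast markers tested were higher in knock-out, with a mean of 0.21 (adjusted p = 0.0998), led by Dcn at 0.39 (SE 0.22) and Ogn at 0.37 (SE 0.23). Knock-out replicate 1 had the highest mean of that list, 4.88 against 3.61 to 4.45 in the other libraries, and without it the mean log2 fold change was -0.023. The list passed without wild type replicate 3 (0.33, adjusted p = 0.0337) or knock-out replicates 2 (0.36, 0.00189) or 4 (0.38, 0.00206). Blood markers (-0.35, 5 of 5 lower, adjusted p = 0.19) and neutrophil and lymphocyte markers (-0.43, 5 of 6 lower, 0.193) were highest in wild type replicate 1, where the list means were 5.10 and 3.30 against at most 3.52 and 2.45 elsewhere. Without that library the mean log2 fold changes were 0.20 and -0.081, and the inhibitory markers passed (-0.084, adjusted p = 0.026). Without wild type replicate 4, mature oligodendrocyte (-0.19, adjusted p = 0.0143), microglia (-0.18, 0.0161) and blood markers (-0.83, 0.0143) passed. Neutrophil and lymphocyte markers did without knock-out replicate 2 (-0.63, 0.0367). With an estimated correlation the lowest adjusted p of any list was 0.915 without wild type replicate 1 and 0.565 without wild type replicate 4.

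Among the other lists, immediate early genes had a mean log2 fold change of -0.11 (13 of 19 lower, camera adjusted p = 0.0527), with Ier2 at -0.45 (SE 0.15) and Junb at -0.26 (SE 0.12), and heat shock and chaperone genes a mean of 0.17 (15 of 19 higher, adjusted p = 0.0527), with Hsp90aa1 at 0.42 (SE 0.22) and Dnaja1 at 0.26 (SE 0.13). Opioid and tachykinin genes (mean 0.021, median -0.12, adjusted p = 0.34) included Oprm1, the mu opioid receptor, at 1.68 ± 1.52 and 4.50 ± 2.13 FPKM (1.14, SE 0.42). Synaptic vesicle genes (0.020, adjusted p = 0.813), neurofilament and axonal cytoskeleton genes (0.10, 0.531; Ank3 at 0.48, SE 0.17), cytokines and chemokines (-0.071, 0.388), interferon-induced genes (-0.047, 0.32) and mitochondrially encoded genes (0.17, 0.507) did not pass. In the mitochondrial list, mt-Co3 at 27.0 ± 14.9 and 69.4 ± 46.4 FPKM (1.24, SE 0.44) has near-identical nuclear copies, and its values are uncertain. Without wild type replicate 1, immediate early genes (-0.15, adjusted p = 0.0108), synaptic vesicle genes (-0.053, 0.0149) and mitochondrially encoded genes (0.45, 4.37e-06) passed. None did with an estimated correlation (adjusted p = 0.915 or higher). The mitochondrial mean was 0.026 without wild type replicate 2. Immediate early genes also passed without wild type replicate 2 (0.0304) or knock-out replicates 1 (0.00031) or 2 (0.0178). Their mean was -0.0086 without knock-out replicate 4. Heat shock genes passed without wild type replicates 3 (0.0337) or 4 (0.00905) or knock-out replicate 2 (0.0163), with a mean of at least 5 FPKM (0.0256), with median-ratio rescaling (0.0498), with quantile normalization (0.00253) and with the length trend removed (0.000606). Their mean was 0.074 without knock-out replicate 1. Interferon-induced genes passed without wild type replicate 2 (-0.11, 0.0441). For the opioid, sensory ganglion, synaptic vesicle and cluster neighbour lists the mean was above 0 while camera pointed down, and for ependymal and mitochondrial genes the median (-0.010 and -0.0077) was below 0 while the mean and camera pointed up.

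Loss of a microRNA is asked about through genes with its site. Of 13058 tested genes with a 3′ UTR, 2674 held a miR-96 site, and their mean log2 fold change was 0.078 (SD 0.18) against 0.0077 (SD 0.20) for genes without one. At equal UTR length and GC content the difference was 0.017, and 2 of the 35 splits of the libraries gave a difference as large in size (share 0.0571, two-sided). Camera gave p = 0.000281 with the preset and p = 0.196 with an estimated correlation. With the length trend removed the difference of these miR-96 seed-site genes was -0.00058, with the length and GC trends removed -0.00099, and without wild type replicate 1 0.0098. Of the site forms, the heptamer TGCCAAA ranked 2385 of 16384 by its difference and 912 by the ratio of the difference to its SE (5.56% of heptamers higher). GTGCCAA ranked 11115 and 9651. By the ratio TGCCAAA ranked 2476 without wild type replicate 1 and 3579 with the length trend removed. Genes with sites of the cluster members miR-182 (TTGCCAA, difference 0.021, share of splits 0.0286) and miR-183 (GTGCCAT, 0.0073, share 0.457) were compared in the same way, and 0.0286 is the smallest share that 35 splits can give. Among all heptamers TTGCCAA ranked 3472 by its difference and 1865 by the ratio (11.4% of heptamers higher). Its difference was 0.014 without wild type replicate 1 and 0.0065 with the length trend removed. Scn1a, Scn2a, Scn3a, Scn8a and Scn9a each held 1 TGCCAAA site in the longest 3′ UTR and Scn2b held 2, while none of the 10 tested channel genes held GTGCCAA. The miR-182 site TTGCCAA differs from GTGCCAA only in its first base, so TGCCAAA, held by 1938 genes, is the form ending in A for both microRNAs. The sites of these channel genes therefore cannot be told from miR-182 sites.

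Around the cluster on chromosome 6, the 20 neighbouring genes tested had a mean log2 fold change of 0.0039 (camera adjusted p = 0.842). Cep41 (chromosome 6, 30653457 to 30693749) had the lowest p of them, with 4.88 ± 0.463 FPKM in wild type and 6.69 ± 0.699 in knock-out (log2 fold change 0.39, SE 0.11, limma adjusted p = 0.62). Within 10 Mb of Mir96, 6 of 101 tested genes had an unadjusted p under 0.05 (Fisher's exact test, two-sided, p = 0.825). Over chromosomes with at least 30 tested genes, the lowest p was on chromosome 17, where the share of such genes was smaller than elsewhere. There 24 of 699 genes had an unadjusted p under 0.05 (odds ratio 0.60, Fisher's exact test, two-sided, p = 0.0108, Benjamini-Hochberg adjusted p = 0.217). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in all 8 libraries, with a mean log2 fold change of 0.31 as a list (4 of 4 higher, camera adjusted p = 0.0801). They passed with quantile normalization (0.28, 0.0444), with library weights (0.42, 0.0192), and without wild type replicate 4 (0.47, 0.0176) or knock-out replicate 3 (0.43, 0.0213).

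The libraries differed in ways that genotype did not explain. Pairwise correlations of log2 values across tested genes ran from 0.955 to 0.991, and those of wild type replicate 1 with the other libraries from 0.955 to 0.969. The first principal component, 46.6% of the variance, set wild type replicate 1 apart (-0.87, with the others between -0.085 and 0.28). In that library the median gene with transcripts over 8000 nt lay 0.42 below its mean over libraries (a deviation of -0.42) and the median gene under 1000 nt lay 0.28 above it. In knock-out replicates 1 and 2 genes over 8000 nt lay 0.23 and 0.17 above. Across the 15023 genes with a length, the log2 fold change correlated with log2 transcript length (r = 0.224, or 0.0893 without wild type replicate 1); genes are not independent replicates, so no p is given.

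**Figure D4:**
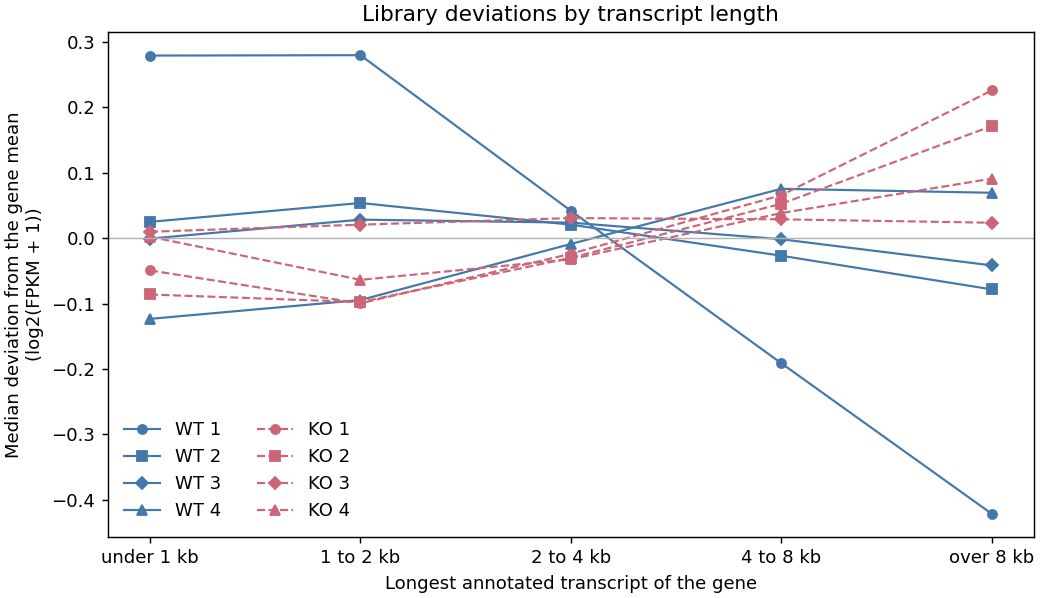
Median deviation of each library from the gene mean, in log2(FPKM + 1), for tested genes in 5 classes of longest annotated transcript. For genes over 8000 nt wild type replicate 1 lay at -0.42 and knock-out replicate 1 at 0.23.

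The second component, 18.1% of the variance, did not follow genotype either. Wild type replicates 2 and 3 and knock-out replicate 3 had scores from 0.33 to 0.63, and the other 5 libraries from -0.33 to -0.20. Some single genes set the libraries apart across genotypes in another way. Thoc2, a gene of the nuclear export complex of mRNA, was at 16.9, 16.8, 16.2 and 31.6 FPKM in wild type replicates 1 to 4 and at 35.1, 33.5, 17.2 and 34.5 in knock-out replicates 1 to 4. The AMPA receptor gene Gria2 was at 40.1, 39.9, 39.8 and 78.5 FPKM in the wild-type libraries and at 77.2, 81.8, 44.8 and 77.8 in the knock-out libraries. Thoc2 and Gria2 were named here after their values had been seen, and no label gives a batch or a date.

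**Figure D5:**
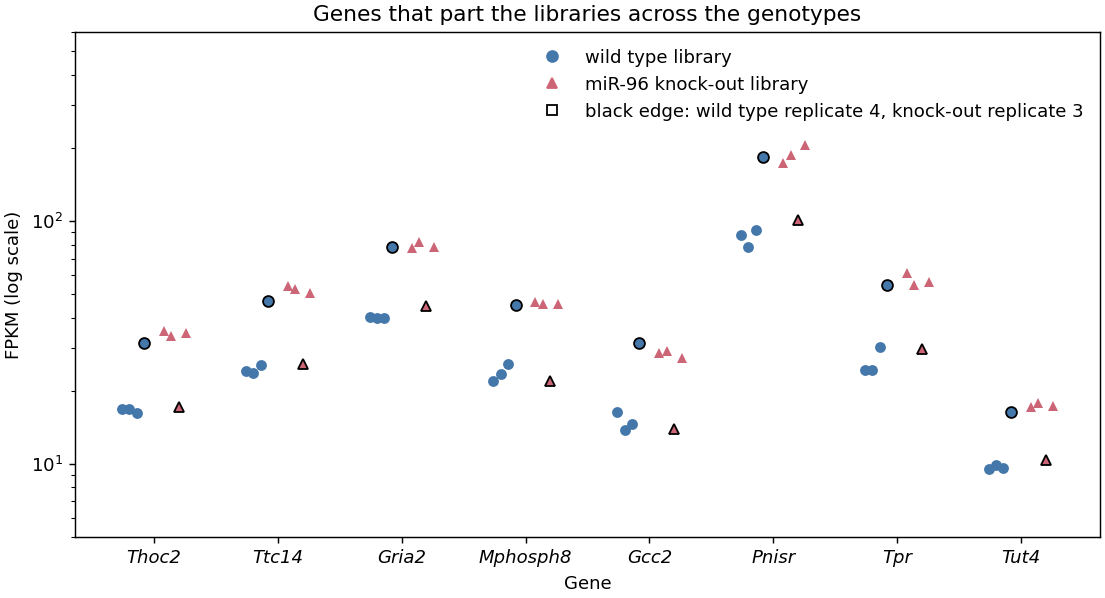
FPKM (log axis) of 8 genes, 1 point per library, with black edges on wild type replicate 4 and knock-out replicate 3. For Thoc2, wild type replicate 4 lay at 31.6, just below the knock-out libraries other than replicate 3 (33.5 to 35.1), and knock-out replicate 3 at 17.2, just above the other wild-type libraries (16.2 to 16.9).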

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

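The split that exchanges 1 library of each genotype was singled out because it gave the most genes, and the tests of it were chosen after that count and the length and GC content of its genes had been seen. The count of splits for genes past the adjusted threshold was likewise chosen after the result was seen.

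In 140 groups of 4 libraries, 7 held 1 library far from the other 3, and chance marks about 1 in 20 groups, 7 here. Ppp2cb was at 55.03 FPKM in wild type replicate 4, against 66.3 to 68.1 in the other wild-type libraries, and Hist1h4i at 4.0961 FPKM in wild type replicate 1, against 3.42 to 3.503. March11 was at 3.1515 FPKM in knock-out replicate 1, against 2.28 to 2.35 in the other knock-out libraries. Knock-out replicate 3 stood apart in 4 groups. Its mitochondrially encoded genes took 4.0432% of all FPKM, against 5.33% to 5.44%, and Scn9a was at 1.3205 FPKM, against 2.17 to 2.33. Its mean log2(FPKM + 1) was 4.3245 for GABA-A and glycine receptor genes, against 4.50 to 4.54, and 3.4969 for sex-linked genes, against 3.96 to 3.99.

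For genes past limma's adjusted threshold the real grouping gave 0 (831 at unadjusted p under 0.05) and the highest of the other splits 1303. Any split reaches a count of 0, so the 35 of 35 that did say nothing about chance. For 3 other counts the splits of the 8 libraries into groups of 4 did not exclude chance. For genes at unadjusted p under 0.05, 7 of 35 splits gave as many as the real 831, with 4334 the highest of the others. With estimated library weights 6 of 35 gave as many as the real 1627 (highest other 3661), and 28 of 35 gave as many gene lists as the real 8 (highest other 18).

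The split that exchanges wild type replicate 4 and knock-out replicate 3 gave 1303 genes, the only split with any, and points to a structure of the libraries other than genotype as labelled. The 846 genes higher on the side of the other knock-out libraries had a median transcript GC content of 41.7% and a median length of 5696 nt, against 51.7% and 1930 nt for the 457 lower genes. With both trends removed 603 genes passed (highest other split 1). This count lay between bounds that were set after the 1303 had been seen and before the test was run. A trend on length and GC content may therefore account for part of the 1303. Labels exchanged between these libraries would leave miR-96 site genes higher in that split, and with both trends removed the site difference was -0.0025275. By the prediction as written, a value at or under 0 counted against exchanged labels, and this value did. It also lies within the range of the other splits (highest 0.0036734), so the test could not decide. Liver-expressed genes followed the labels as given, with Alb at 0.0301 FPKM in wild type replicate 4 and 33.0 in knock-out replicate 3. This would count against exchanged labels only if these genes go with genotype, and their source is itself open. A library or sequencing batch could give the same structure and cannot be told apart from exchanged labels, because no label gives a batch and Mir96 was listed at 0 in every library.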

How the results depend on the processing

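The alternatives that remove trends on transcript length and GC content, the wider ribosomal rule, and the estimated correlation under each other setting were chosen after the data had been seen. No alternative run here gave a gene past limma's adjusted threshold, except library weights and the fit without knock-out replicate 2. Pseudocount, filter of 5, rescaling, eBayes options and the wider ribosomal rule kept the number of lists within 1.5 times of 8. Of 150 values of the main results over all alternatives, 106 stayed the same. For a count this means within 1.5 times of the main count, and for an effect the same direction and side of the threshold. Of the rest, 36 counts moved by over 1.5 times (among them the list counts with an estimated correlation), 2 values reversed, 4 lost the threshold and 2 gained it. Of 1150 values of single genes and lists, 983 kept direction and side of the threshold, 66 reversed, 35 lost the threshold and 66 gained it. Depth was estimated and limits the genes under 1 FPKM, which were tested only without the filter. Except where a setting tests more genes or fewer libraries, the cause was not tested.

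Without the filter 1396 genes had unadjusted p under 0.05, and the mean of the cluster neighbours was -1.8e-06. The GABA-A (adjusted p = 0.0914) and histone calls (0.682) ended without it, and the target (0.0576) and histone calls (0.0693) with library weights, which added the sex-linked (0.0192) and mitochondrial lists (0.000273). With a mean of at least 5 FPKM the opioid list was at -0.19, and with median-ratio rescaling the neighbours at -0.0013. Median-ratio rescaling added the sodium channel, immediate early and heat shock lists (0.0498 for each), the filter of 5 the opioid (0.0325) and heat shock lists (0.0256), and no filter the sodium channel and immediate early lists (0.0429 for both). With quantile normalization 17 lists passed, adding sodium channels, potassium channels, immediate early genes, neurofilament genes and mitochondrially encoded genes (0.0127 for each), heat shock genes (0.00253), sex-linked genes and meningeal markers (0.0444 for both) and astrocyte markers (0.0461), and Scn4b was at 0.048, the opioid list at -0.014, sensory ganglion markers at -0.032 and the neighbours at -0.011. With library weights 1627 genes passed, 1012 higher and 615 lower, 5014 had unadjusted p under 0.05, and the site difference was 0.0158 (share of splits 0.0286). Under these weights (5.09 for wild type replicate 3, 0.153 for replicate 1) the means were 0.026 for excitatory, -0.12 for motor, -0.23 for sensory ganglion, -0.038 for astrocyte, 0.052 for endothelial, -0.10 for meningeal, -0.071 for ependymal, 0.011 for blood and 0.024 for neutrophil and lymphocyte markers, 0.077 for interferon-induced genes and -0.063 for the neighbours.

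With the length trend removed 5 lists passed, among them heat shock (0.000606) and mitochondrially encoded genes (0.0351), the sodium channel mean was 0.038 and the difference of miR-96 seed-site genes -0.00058, and the means were -0.0017 for oligodendrocyte precursors, -0.012 for astrocytes, -0.062 for synaptic vesicle genes and -0.027 for the neighbours. With the length and GC trends removed 4 lists passed, the sodium channel mean was 0.0078 and the difference of those genes -0.00099, with Scn3b at -0.0088, Scn3a at -0.041 and Scn7a at -0.058. The means were then -0.0031 for calcium channels, -0.0040 for glutamate receptors, -0.019 for reported targets, -0.0055 for oligodendrocyte precursors, -0.025 for astrocytes, -0.064 for synaptic vesicle genes and -0.038 for the neighbours. With an estimated correlation 0 lists passed in limma's camera (8 with the preset), and the sodium channel mean of 0.19 had p = 0.219. Under each other setting 0 lists passed with it. Genes with 2 or more sites differed by 0.041 (share of splits 0.0286), those with a site joining both forms by 0.017 (0.114), and site genes without covariates by 0.071 (0.114).

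With the replicate number as a replicate block 13 lists passed, 0 genes passed and 790 had unadjusted p under 0.05, and the sodium channel mean was 0.19. Sodium channels (adjusted p = 0.0429 against 0.0527), immediate early (0.0376), heat shock (0.0279) and sex-linked genes (0.0398) and meningeal markers (0.0206) passed under the block and not without it. Correlations of same-numbered libraries were -0.108, -0.0551, 0.0241 and 0.144, so the numbers were not taken to pair animals.

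Leaving out 1 library gave 0 to 1 genes past the threshold, 0 to 1 higher, 325 to 3151 at unadjusted p under 0.05, 6 to 15 lists, and a sodium channel mean of 0.10 to 0.27. The ranges that crossed 0 were -0.046 to 0.17 for Scn2b, -0.15 to 0.050 for Scn4b, -0.039 to 0.14 for Scn3b, -0.11 to 0.0098 for excitatory, -0.084 to 0.011 for inhibitory, -0.091 to 0.40 for motor, -0.14 to 0.17 for sensory ganglion, -0.19 to 0.024 for oligodendrocyte, -0.0098 to 0.052 for astrocyte, -0.18 to 0.047 for microglia, -0.034 to 0.042 for endothelial, -0.023 to 0.38 for meningeal, -0.057 to 0.19 for Schwann cell, -0.086 to 0.32 for ependymal and -0.83 to 0.20 for blood markers. They were -0.022 to 0.060 for opioid, -0.11 to 0.039 for interferon-induced, -0.053 to 0.063 for synaptic vesicle genes and -0.014 to 0.026 for the neighbours.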

Other observations

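The lists of liver, muscle, kidney and pancreas genes, the test of other organs and the test of induction in liver genes were chosen after the liver genes had been seen, as were the tests with the length and GC trends removed and the test of ribosomal genes without wild type replicate 1.

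Heat shock and chaperone genes were the one list that passed with the length and GC trends removed and not as deposited, with a mean log2 fold change of 0.19 (limma camera adjusted p = 0.000248) against 0.17 (0.0527). Knock-out replicate 1 had the highest mean of that list, 7.08 on the log2(FPKM + 1) scale against 6.42 to 6.87 in the other libraries, and without it the mean as deposited was 0.074 (adjusted p = 0.498). With an estimated correlation the adjusted p was 0.768 as deposited and 0.997 with both trends removed. The members of lowest p were Hsp90aa1 and Dnaja1, a chaperone of the HSP90 family and a co-chaperone of the HSP40 family.

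Liver-expressed genes had higher values in the knock-out libraries, and in a second list of 60 such genes, whose values had not been looked at, 32 of the 35 with a mean of at least 0.1 FPKM (91.429%) had a higher knock-out mean. Their medians were 0.274, 0.262, 0.0341 and 0.0847 FPKM in wild type replicates 1 to 4 and 0.283, 0.677, 0.597 and 0.73 in knock-out replicates 1 to 4. No p is given, since this list was written after liver genes had been seen to separate these libraries. Of the muscle, kidney and pancreas genes 29.412% were higher (1 of 11, 4 of 4 and 0 of 2). The muscle genes set this share and gave no sign of more muscle RNA in the knock-out libraries. Too few kidney and pancreas genes reached 0.1 FPKM to decide about RNA from other organs in general. Induction that needs the knock-out stays open. The highest wild-type median was 0.96683 times the lowest knock-out median (0.597 in the first liver list). This rests on 1 library per genotype, its bounds were set after the medians had been seen, and it replaced a first form that had grouped libraries by their values. A small amount of RNA or reads from liver, more of it in the knock-out libraries, may account for these genes, and of the 13 second-list genes at 0.1 FPKM or more in every library, expression in the cord itself stays open.

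For the higher mean of the sodium channel list, 5 of the 35 splits, the real one included, gave a mean as large in size (real value 0.19, highest other 0.25), so chance could not be excluded. Long transcripts may account for it, since its mean lay at the 94.36th percentile of 10000 random lists matched on transcript length and level, inside the central 95%. Loss of repression by miR-96 predicts a shift of all genes with a site, and the shift was 0.016729 (2 of 35 splits as large, real value 0.017, highest other 0.020). For these miR-96 seed-site genes it was 0.0098 without wild type replicate 1, -0.00058 with the length trend removed and -0.00099 with both trends removed, where it was not beyond the splits (shares 0.886 and 0.686). The trends were fitted on all tested genes, site genes included, so their removal may also have taken out part of a real shift. Values after it therefore do not count against repression by miR-96. By the prediction as written, a share of 0.05 or more counted against this explanation, and the share of 0.0571 did. It did so narrowly, since 0.0571 is next to the smallest share that 35 splits can give. All site genes are a wider set than the channels, so for the channels by themselves the test could not decide. The TGCCAAA sites of the channels also match miR-182, so they are not particular to miR-96. The 6 channel genes with a site had a mean log2 fold change of 0.31 and the 4 without 0.011, but their median transcript lengths were 9247.5 and 4566 nt, and with the length trend removed the means were 0.091 and -0.042.

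For the ribosomal protein genes, 9 of the 35 splits gave a mean as large in size (real value 0.338, highest other 0.484), the mean lay at percentile 0 of random lists matched on transcript length and level, and without wild type replicate 1 it was -0.11363. With the wider reading of the symbol rule the mean over 98 genes was -0.29 (limma camera adjusted p = 1.34e-14) and 8 of 35 splits gave as much. This reading was run first, and the reading adopted later gave the larger mean. For the respiratory chain genes, 7 of the 35 splits gave a mean as large in size (real value 0.232, highest other 0.339). Their mean lay at the 0.03rd percentile of matched random lists. The same ranking gave percentiles of 0 for cholesterol synthesis, 19.02 for histone genes, 53.6 for calcium channels, 70.2 for reported targets, 80.8 for glutamate receptors, 90.7 for potassium and HCN channels and 100 for GABA-A and glycine receptors. Members of a list varied together (estimated correlation 0.91 for ribosomal, 0.63 for respiratory chain, 0.34 for cholesterol synthesis and 0.48 for GABA-A and glycine receptor genes). Members of random lists were drawn separately, so the spread of those lists may be too narrow. Percentiles near 0 or 100 therefore do not by themselves place a list beyond transcript length. With the length trend removed the means were -0.24 for ribosomal (limma camera adjusted p = 1.26e-15) and -0.14 for respiratory chain genes (3.15e-11). With both trends removed they were -0.24 (2.21e-14) and -0.15 (3.52e-11). The fitted trends thus did not account for these whole means. With an estimated correlation no list passed at either setting (lowest adjusted p 0.99685).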
